A study of Homo sapiens with 17 samples.

How the data were processed

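RNA was measured by sequencing in Jurkat cells, an established human line of T cell acute lymphoblastic leukaemia, after exposure to ILT3.Fc. ILT3.Fc is a soluble protein that joins the extracellular part of the inhibitory receptor ILT3 (gene LILRB4) to an antibody Fc fragment. Per the labels' protocols, cells were grown in RPMI-1640 with fetal bovine serum, RNA was purified with an RNeasy Mini kit, and polyadenylated RNA was made into libraries with a TruSeq RNA kit. The labels give 3 doses (0, 12.5 and 25 µg/ml) and 3 times (6, 12 and 24 h). They state that each sample was duplicated and do not say whether the duplicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

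The authors deposited 1 table of FPKM values (fragments per kilobase of gene model, scaled to the mapped fragments of each library), with a column for each library. The submitters' processing notes name TopHat2 2.1.0. The quantifier, genome build and annotation are not given in the sources used here, so no coordinates are printed. The table held 25593 lines for 25548 gene symbols. Of 45 repeated symbols, the line with the highest mean was kept. 5290 symbols (20.7%) were listed at 0 in every library, and an FPKM of exactly 0 can be a failed estimate.

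FPKM keeps no read counts, so no test on whole reads was run. Relative depth was recovered from 5552 genes with a mean FPKM below 0.3, whose smallest values differ between libraries by the worth of 1 fragment (tolerance 0.03 on the log2 scale). It ranged from 0.67 to 1.00 of the deepest library, and the absolute depth is unknown. Sums of FPKM ranged from 504363 to 557389.

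The 12015 genes with a mean FPKM of at least 1 over all 17 libraries (47% of symbols) were tested on log2(FPKM + 1). A fold change on this scale understates the change of genes with low values. limma 3.58.1 in R 4.3.3 fitted 1 mean for each of 9 groups of dose and time, with 8 residual degrees of freedom, so that all groups shared 1 estimate of the spread per gene. Empirical Bayes moderation used a trend on mean expression and added 3 prior degrees of freedom. The single untreated library at 12 h was thereby assumed to vary like the other groups. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Effects over all times are the mean of the effects at 6, 12 and 24 h.

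Of 36 gene lists written before the data were examined, the 30 with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01. Each call was repeated with an estimated correlation. fry, which asks whether the members of a list move one way on balance without comparing them with other genes, was also run. Counts of members are given over all genes tested and adjusted over the list alone. The design, the main tests, the lists, the rule for naming genes and all alternatives but 3 were also chosen before the data were examined. The 3 added later leave out the 24 h libraries, correct each library for GC content and gene length, and join that correction to the replicate block.

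Genes were named by a fixed rule. For 25 against 0 µg/ml over all times, it took the 12 genes with the largest rise and the 12 with the largest fall among those called with 1 sign at all 3 times. For the other main comparisons it took 4 of each. It also took up to 4 members of each list with the smallest p, and fixed candidate genes. Any other gene is said to have been chosen after its values were seen. Some genes that were counted are not reported here by name.

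GC content and length came from GENCODE v29 (GRCh38), matched by symbol for 11121 of the 12015 genes (92.6%). The build may differ from the one used for the table, and no position was taken from it. The correction subtracted a loess curve (span 0.3) of each library's deviation from the mean library on GC content, then on length. Other alternatives changed the pseudocount to 0.1, dropped the filter or raised it to a mean FPKM of 5, centred libraries on their medians, applied quantile normalization, or dropped the variance trend. Further ones added sequencing lane as a covariate, used each lane alone, fitted only the groups compared, used an additive or a linear dose model, left out 12 h libraries, added the replicate number as a block, or left out each library in turn.

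The calling steps were tested on simulated data with 200 of the 12015 genes changed, in 20 simulations. For 25 against 0 µg/ml over all times, 66.6% of genes changed by 0.25 on the log2 scale and 93.2% of those changed by 0.5 were recovered, and 5.1% of calls were false. At 12 h, with 1 untreated library, 13.4% and 62.1% were recovered, against 26.2% and 77.1% at 24 h. A simulated list of 25 genes shifted by 0.1 was called in 20 of 20 simulations. The simulations drew genes independently, without correlation between genes and without bias of single libraries with GC content or length. These rates may therefore be too favourable for the real libraries.

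The table does not separate strands, so genes overlapping an antisense partner are uncertain, as are near-identical copies and read-through genes. Small structured RNAs are poorly captured by poly(A) selection and are given with that limit. The untreated 12 h group held 1 library, and its duplicate is not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.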

Results

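The data comprised 17 RNA-seq libraries of Jurkat cells exposed to ILT3.Fc at 0, 12.5 or 25 µg/ml for 6, 12 or 24 h, made to find the regulator behind the response to the protein. There were 8 groups with 2 libraries each, and the untreated 12 h group held 1. All 24 h libraries and replicate 1 of each 6 h group ran in lane 4, and all 12 h libraries and replicate 2 of each 6 h group ran in lane 5. Each library had 11842 to 12016 genes at an FPKM of 1 or more, and its 10 most abundant genes took 4.01% to 4.54% of the summed FPKM. Duplicates correlated at 0.9795 to 0.9863 across genes, which are not independent replicates, and no pair of libraries was identical. Replicate 1 of 12.5 µg/ml at 6 h stood apart, with the highest FPKM sum and deviations from the mean library that followed gene length (Spearman correlation of -0.64 across genes). Replicate 2 of 25 µg/ml at 24 h had the lowest median correlation to the other libraries (0.9767), and its deviations followed GC content (Spearman correlation of 0.57 across genes).

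Exposure to 25 µg/ml was first compared with untreated cells over all times, to ask which transcripts followed ILT3.Fc. Genes of cholesterol synthesis rose. HMGCS1, which encodes the cytosolic enzyme that makes HMG-CoA for the mevalonate pathway, rose by 0.66 on the log2 scale (SE 0.026, limma adjusted p = 3e-07). The sterol synthesis enzymes HSD17B7 and MSMO1 rose by 0.54 (SE 0.056, adjusted p = 3.45e-04) and 0.50 (SE 0.037, adjusted p = 5.9e-05), and the squalene synthase gene FDFT1 by 0.31 (SE 0.027, adjusted p = 1.67e-04). Of 23 measured members of the cholesterol synthesis list, 17 rose, none fell and 6 did not pass, and 19 rose when adjusted over the list alone. Without the 24 h libraries FDFT1 stood at 0.19 (adjusted p = 0.0983). The median member changed by 0.22, and camera called the list (adjusted p = 5.41e-18, and adjusted p = 9.24e-04 with an estimated correlation). At 24 h HMGCS1 stood at 67.2 ± 2.82 FPKM in untreated cells, 96.5 ± 0.412 at 12.5 µg/ml and 132.8 ± 3.90 at 25 µg/ml (SD, n = 2 each).

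Genes of mitosis fell with the same dose. HMMR, which encodes a spindle-associated hyaluronan receptor, fell by 0.52 (SE 0.035, limma adjusted p = 2.6e-05), and the mitotic kinase gene PLK1 fell by 0.44 (SE 0.028, adjusted p = 2.24e-05). The mitotic kinesin gene KIF20A fell by 0.40 (SE 0.027, adjusted p = 2.82e-05), and CENPA, the centromeric histone, by 0.33 (SE 0.026, adjusted p = 8.96e-05). In the G2/M list 29 of 35 measured members fell, none rose and 6 did not pass, and 33 fell when adjusted over the list alone. The median was -0.22, and the list was called (camera adjusted p = 3.04e-36, and adjusted p = 6.55e-04 with an estimated correlation). PLK1 at 24 h was 106.9 ± 2.05 FPKM untreated, 85.3 ± 1.10 at 12.5 µg/ml and 66.7 ± 5.12 at 25 µg/ml (SD, n = 2 each).

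**Figure D1:**
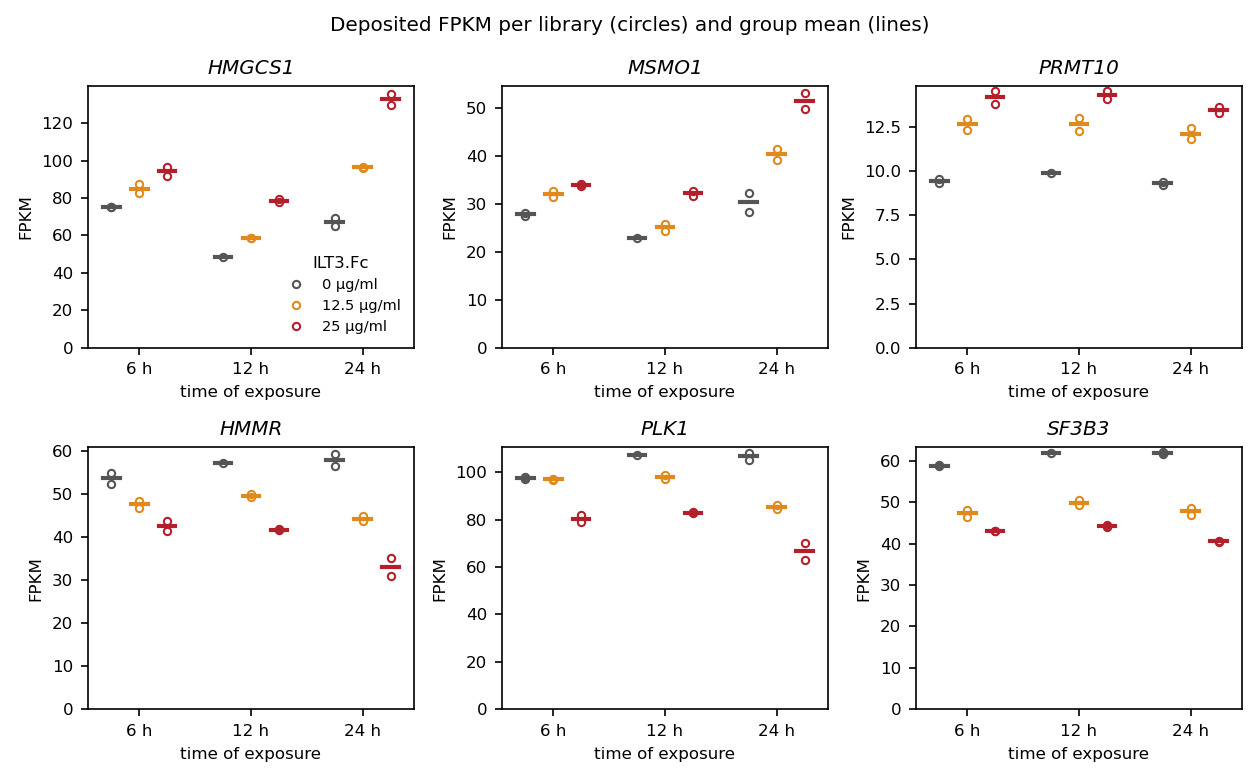
FPKM of HMGCS1, MSMO1, PRMT10, HMMR, PLK1 and SF3B3 (vertical axes, from 0) against hours of exposure (horizontal axes) in Jurkat cells at 0, 12.5 and 25 µg/ml ILT3.Fc, with a circle for each library and lines through the group means. HMGCS1 reached 132.8 FPKM at 25 µg/ml and 24 h, against 67.2 in untreated cells.

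Several genes outside these groups were among those that changed most. SF3B3, a subunit of the SF3B splicing complex, fell by 0.51 (SE 0.020, limma adjusted p = 3e-07), and PRMT10, of the protein arginine methyltransferase family, rose by 0.51 (SE 0.029, adjusted p = 1.08e-05). CHORDC1, a co-chaperone of HSP90, fell by 0.47 (SE 0.035, adjusted p = 6.36e-05). PTCRA, the alpha chain of the pre-T cell receptor, fell by 0.51 (SE 0.066, adjusted p = 0.00138), and the orphan receptor gene GPR17 fell by 0.68 (SE 0.067, adjusted p = 2.5e-04). HYAL3, C6orf226, LOC645249, LOC100506233, LOC100506518 and the small nucleolar RNA gene SNORA32 also fell, by 0.44 to 0.59, and C6orf226 was at -0.31 without the 12 h libraries (adjusted p = 0.174). C1orf216, the tRNA-modifying enzyme gene TRMU, the interferon-induced gene IFI44, CRYL1, LOC100289187, LOC100505815 and LOC100507558 rose by 0.41 to 0.50. LOC100505815 was at 0.27 in lane 4 (adjusted p = 0.525) and 0.31 without the 12 h libraries (adjusted p = 0.27), and lost its call under 18 of 32 alternatives. LOC100507558 was at 0.28 without the 12 h libraries (adjusted p = 0.101), and SNORA32 lost its call under 12 of 33 alternatives. The small Cajal body RNA SCARNA15 passed the test, but it was listed at 0 in the untreated 12 h library and poly(A) libraries measure it poorly, so no fold is given.

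In all, 1138 genes were called, of which 657 were higher and 481 lower, and 3116 had an unadjusted p under 0.05. The median size of the called changes was 0.18, and 15 genes changed by at least 0.5. The split followed the scaling: 393 higher and 765 lower after median centring, 539 and 653 after quantile normalization, and 942 and 1185 after correction for GC content and length. Lane 4 alone, without 12 h libraries, gave 42 calls (12 higher and 30 lower, 29 of them among the 1138), and lane 5 alone, without 24 h libraries, gave 8 (5 higher and 3 lower, 4 among the 1138). HMGCS1 rose by 0.66 (adjusted p = 0.00382) in lane 4 and 0.49 (adjusted p = 0.0269) in lane 5, and SF3B3 fell by 0.52 (adjusted p = 0.00468) and 0.46 (adjusted p = 0.0411). PLK1 changed by -0.47 in lane 4 (adjusted p = 0.0414), and its value in lane 5 was -0.34 (adjusted p = 0.0732). HSD17B7 passed in neither lane (0.57 and 0.46, adjusted p = 0.0548 and 0.137), and nor did MSMO1 (0.52 and 0.37, adjusted p = 0.0586 and 0.12) or PTCRA (-0.46 and -0.54, adjusted p = 0.107 and 0.137). HMMR, KIF20A, CENPA, FDFT1, PRMT10, CHORDC1 and GPR17 passed in lane 4 and not in lane 5. Of 80 genes singled out among the calls, 14 passed without the 24 h libraries and 45 without the 12 h libraries, and the values of 26 and 4 moved by over 1.5 times. The cholesterol synthesis list had medians of 0.25 (camera adjusted p = 8.72e-17) and 0.09 (2.05e-05) in lanes 4 and 5, and the G2/M list -0.23 (2.05e-31) and -0.14 (6.77e-19). Leaving out 1 library gave 738 or 690 calls for the untreated 24 h replicates, 688 or 613 for the untreated 6 h ones, 721 or 641 for 25 µg/ml at 6 h, and 689 or 641 for 25 µg/ml at 12 h. It gave 2034 or 2032 for the 12.5 µg/ml 6 h replicates.

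Another 4 of the 30 lists tested were called lower by camera over all times, each with a call that was lost with an estimated correlation. As many lists or more were called in 30 of 100 splits with exchanged dose labels, the real one included. After correction for GC content and length the histone call was lost too (camera adjusted p = 0.132), and the others were kept. In the heat shock list CHORDC1, HSPH1 and HSPE1, all chaperones or co-chaperones, fell and the other 15 of 18 members did not pass. It had 6 falling when adjusted over the list alone, a median of -0.05 and camera adjusted p = 6.96e-05 (adjusted p = 0.351 with an estimated correlation). The G1/S list, genes of DNA replication, had 5 of 34 members falling, among them MCM5, MCM6, UHRF1 and POLA1, the last chosen after its values were seen, and none rising. It had 6 falling adjusted over the list alone, and its median was -0.04 (adjusted p = 3.02e-04, and adjusted p = 0.153 with an estimated correlation). MCM5 fell by 0.15 and MCM6 by 0.14. Without the 24 h libraries the values were -0.07 for MCM6, -0.04 for HSPH1, -0.07 for HSPE1 and -0.07 for DKC1, and none passed. HSPE1, DKC1 and EBNA1BP2 lost their calls under 21, 19 and 20 of 33 alternatives. The list of MYC targets and ribosome biogenesis had 2 of 32 members falling, DKC1 (-0.11) and EBNA1BP2 (-0.14), none rising, none adjusted over the list alone, and adjusted p = 3.02e-04 (adjusted p = 0.383 with an estimated correlation). Replication histones, whose messages mostly lack poly(A) tails, had no call among 7 over all genes, a median of -0.25, 1 falling adjusted over the list alone, and adjusted p = 0.0224 (adjusted p = 0.153 with an estimated correlation). Within lanes, the heat shock list had medians of -0.09 and -0.02 (camera adjusted p = 5.69e-07 and 0.4), the G1/S list -0.01 and -0.08 (0.21 and 6.51e-06), the MYC list -0.04 and -0.04 (0.0065 and 0.00952), and the histones -0.31 and -0.16 (0.0065 and 0.4). By fry, 15 lists were called.

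Lists tied to T cell signalling were not called by camera, while fry called the T cell receptor (adjusted p = 0.00527), mTORC1 and S6 kinase (adjusted p = 0.0112) and inhibition and anergy lists (adjusted p = 0.0145). The mTORC1 and S6 kinase list had 4 of 19 members rising, RPS6KB1 (0.24), TSC1 (0.18), SESN1 (0.14) and EIF4B (0.12), with none falling (camera adjusted p = 0.37). RPS6KB1, which encodes S6 kinase, rose with limma adjusted p = 0.00305 (SE 0.036), but its rise of 0.23 within lane 4 and 0.29 within lane 5 did not pass (adjusted p = 0.184 and 0.137). Of 22 T cell receptor signalling genes, PLCG1 (0.15), CD28 (0.14) and GRAP2 (0.09) rose, none fell, and the list had adjusted p = 0.0869. The mTORC1 and T cell receptor lists had the same counts adjusted over the list alone. Early activation genes had 2 of 14 falling, IER3 (-0.43) and KLF10 (-0.17; 1 rising and 2 falling adjusted over the list alone), with adjusted p = 0.135. The inhibition and anergy list had 1 of 7 rising, DGKA (0.20; 2 adjusted over the list alone), a diacylglycerol kinase that dampens receptor signals (adjusted p = 0.187). NOTCH targets had PTCRA and SHQ1 falling among 12 (1 rising and 3 falling adjusted over the list alone; adjusted p = 0.243). Among 29 transcription factors of T-ALL and thymocytes, 4 rose, among them STAT3, STAT5B and TRIB2, and LMO1 and ID1 fell (4 and 4 adjusted over the list alone), with a median of 0.01, a test direction of down and adjusted p = 0.955. LMO1 was chosen after its values were seen. Without the 24 h libraries SESN1 (0.09), CD28 (0.09), PLCG1 (0.10) and SHQ1 (-0.02) did not pass, and nor did STAT5B (0.06) without the 12 h libraries. SHQ1, KLF10, STAT5B and GRAP2 lost their calls under 22, 21, 15 and 14 of 33 alternatives. The ALCAM value was 0.01 (SE 0.048, adjusted p = 0.938), and CD6, MYC, NOTCH1, TAL1, GATA3, CD3E and CD69 did not pass either (adjusted p from 0.241 to 0.947), although CD6, a receptor for ALCAM, rose by 0.19 at 24 h (adjusted p = 0.0382). BCL6, DUSP10, SOCS1 and IL2RA had mean FPKM below 1 and were not tested, and LILRB4 was listed at 0 in all 17 libraries.

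The remaining lists were not called by camera for 25 µg/ml over all times either. By fry 6 of them passed: autophagy and lysosome (adjusted p = 0.00527), p53 targets (0.0145), NFE2L2 targets (0.0409), SRF targets (0.0409), interferon (0.0462) and fatty acid synthesis (0.0493). The interferon list had IFI44 (0.44), XAF1 (0.21), STAT2 (0.20), SP100 and SP110 rising and OAS3 (-0.24) falling among 32, with a median of -0.004, a mean of 0.03, a test direction of up and 6 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.484). Glycolysis had 4 of 21 rising, among them ALDOC (0.37) and PFKFB4 (0.32; 5 rising and 1 falling adjusted over the list alone, adjusted p = 0.187). Fatty acid synthesis had 4 of 13 rising, among them ACLY (0.09; 5 rising adjusted over the list alone, adjusted p = 0.135). Autophagy and lysosome genes had CTSB, CTSD, NEU1 and PSAP rising and 1 member falling among 21 (6 and 3 adjusted over the list alone, adjusted p = 0.135). Endoplasmic reticulum stress had 1 of 20 falling, the chaperone HSP90B1 (-0.19; 2 falling adjusted over the list alone, adjusted p = 0.135). Hypoxia had INSIG2 rising and PDK1 falling among 17 (1 and 1 adjusted over the list alone, adjusted p = 0.704). FOXO targets had SESN1 rising and CDKN1B falling among 13, with a median of 0.02, a test direction of down and 2 rising and 1 falling adjusted over the list alone (adjusted p = 0.955). Apoptosis regulators had MCL1 falling among 24, with a median of 0.006, a test direction of down and 0 adjusted over the list alone (adjusted p = 0.593). A single member was called among 40 oxidative phosphorylation genes (NDUFA2, lower), 30 ATF4 targets (SHMT2, higher), 17 NFE2L2 targets (OSGIN1, higher), 65 ribosomal proteins (RPL13A, higher) and 16 NF-kB targets (IER3, lower, against a list median of 0.08). Adjusted over the list alone these counts were 0, 1, 1, 0 and 1, with camera adjusted p of 0.175, 0.299, 0.2, 0.593 and 0.29. SRF targets had CNN2 and ZYX rising among 15 (2 adjusted over the list alone, adjusted p = 0.187). Adhesion genes had ITGAL rising and CXCR4 falling among 21 (2 and 2 adjusted over the list alone, adjusted p = 0.955), and p53 targets had SESN1 and TNFRSF10B rising among 21 (2 adjusted over the list alone, adjusted p = 0.593). No member passed among 4 LXR targets, 6 metallothioneins, 5 NK, 3 B cell, 3 myeloid, 1 erythroid and 1 epithelial markers tested, and adjusted over the list alone 1 LXR target was lower and none of the others changed. SP100, SP110 and CTSB were chosen after their values were seen. Several of these values moved by over 1.5 times without the 24 h libraries, and none of those then passed: ALDOC was at 0.14, PFKFB4 at 0.20, STAT2 at 0.12, ACLY at 0.04, CTSD at 0.01, NEU1 at 0.05, PSAP at 0.07 and PDK1 at -0.07. In the same way SESN1 was at 0.09, SHMT2 at 0.09, RPL13A at 0.13, CNN2 at 0.06, ZYX at 0.05, ITGAL at 0.11 and CXCR4 at -0.07. Without the 12 h libraries INSIG2 was at 0.06 and did not pass. ACLY lost its call under 27 of 33 alternatives, NEU1, MCL1, NDUFA2 and INSIG2 under 17 each, RPL13A under 16 and CXCR4 under 14. In lanes 4 and 5, ALDOC was at 0.53 and 0.12 (adjusted p = 0.0502 and 0.315) and PFKFB4 at 0.45 and 0.13 (adjusted p = 0.0647 and 0.484).

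The effect of 25 µg/ml was then taken at each time, to ask when the response appeared. SF3B3 fell and HMGCS1 and PRMT10 rose at 6, 12 and 24 h. At 6 h SF3B3 fell by 0.44 (SE 0.033, limma adjusted p = 3.74e-04), PRMT10 rose by 0.54 (SE 0.047, adjusted p = 0.00119) and HMGCS1 rose by 0.32 (SE 0.041, adjusted p = 0.0178). DDTL (-0.54), HYAL3 (-0.52) and LOC100288842 (-0.78) also fell at 6 h, and KRCC1 (0.42) and C1orf216 (0.40) rose. Calls were lost under 19 of 28 alternatives for KRCC1, 14 of 28 for C1orf216, 19 of 27 for HYAL3, 17 of 27 for LOC100288842 and 8 of 28 for HMGCS1. PLK1 (-0.28, adjusted p = 0.0423), HMMR (-0.33, adjusted p = 0.0481) and KIF20A (-0.29, adjusted p = 0.0396) had already fallen. The 27 calls comprised 7 higher and 20 lower genes (1239 at an unadjusted p under 0.05). The G2/M list fell (median -0.10, 3 of 35 members fell, 12 adjusted over the list alone, camera adjusted p = 1.51e-12, and adjusted p = 0.0262 with an estimated correlation). Cholesterol synthesis was called higher with 1 of 23 members called, 4 adjusted over the list alone (median 0.07, adjusted p = 3.57e-04, and adjusted p = 0.104 with an estimated correlation). Endoplasmic reticulum stress genes (-0.09, adjusted p = 8.55e-05, and adjusted p = 0.104 with an estimated correlation) and early activation genes (-0.15, adjusted p = 0.00244, and adjusted p = 0.429 with an estimated correlation) were called lower with no member passing over all genes. They had 5 and 2 members lower adjusted over the list alone. Leaving out any 1 library moved the count to between 3 and 8, except the untreated 12 h library (27), either 25 µg/ml 24 h library (21) and either 12.5 µg/ml 6 h library (93).

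HMGCS1, PRMT10 and SF3B3 changed at 12 h too, where 6 genes were called against a single untreated library. HMGCS1 rose by 0.69 (SE 0.051, limma adjusted p = 3.84e-04), PRMT10 by 0.49 (SE 0.058, adjusted p = 0.0105) and INSIG1, which encodes a sterol-sensing regulator of SREBP, by 0.37 (SE 0.052, adjusted p = 0.041), a call lost under 16 of 27 alternatives. SF3B3 fell by 0.48 (SE 0.040, adjusted p = 6.92e-04), and the small RNAs SCARNA15 and SNORA16B were called from values listed at 0, the first in the untreated library and the second in both treated ones. The 4 higher and 2 lower calls became 3 and 7 after median centring, and 1034 genes had an unadjusted p under 0.05. The G2/M list was called lower with no member called, 18 lower adjusted over the list alone, a median of -0.18 and camera adjusted p = 3.29e-27 (adjusted p = 0.00187 with an estimated correlation). Cholesterol synthesis was called higher with 2 of 23 members rising, 8 adjusted over the list alone, a median of 0.17 and adjusted p = 1.19e-12 (adjusted p = 0.00326 with an estimated correlation). G1/S genes were called lower with no member called, over all genes or adjusted over the list alone (median -0.07, adjusted p = 9.67e-08, and adjusted p = 0.0351 with an estimated correlation). NOTCH targets (median -0.06), MYC targets (-0.06) and ATF4 targets (0.06) were called with no member passing and lost with an estimated correlation (adjusted p = 0.283, 0.419 and 0.375 with an estimated correlation). Without either 12.5 µg/ml 6 h library 39 genes were called, and without either 25 µg/ml 24 h library 10.

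At 24 h cholesterol synthesis and mitosis showed their largest changes of the 3 times. HMGCS1 rose by 0.97 (SE 0.041, limma adjusted p = 1.11e-06), MSMO1 by 0.75 (SE 0.059, adjusted p = 9.83e-05), HSD17B7 by 0.65 (adjusted p = 0.0014) and FDFT1 by 0.54. Of the cholesterol synthesis list 22 of 23 members rose (22 adjusted over the list alone), with a median of 0.47 and camera adjusted p = 2.62e-18 (adjusted p = 8.67e-04 with an estimated correlation). HMMR fell by 0.80 (SE 0.056, adjusted p = 4.41e-05), PLK1 by 0.68 (SE 0.045, adjusted p = 3.67e-05) and CHORDC1 by 0.74 (SE 0.057, adjusted p = 9.01e-05). Of 35 G2/M members 29 fell (31 adjusted over the list alone), with a median of -0.38 and adjusted p = 1.31e-32 (adjusted p = 8.67e-04 with an estimated correlation). PLAC8L1 (0.95, adjusted p = 0.00642) and RAET1L, a ligand of the NKG2D receptor (1.12, adjusted p = 0.0331), rose, and the latter lost its call under 7 of 27 alternatives. Both stood near the filter of 1 FPKM. Over all times PLAC8L1 had means of 1.152 FPKM untreated and 1.611 at 25 µg/ml, and RAET1L 1.106 and 1.659. RN5S3, RNU6ATAC, SCARNA4 and SNORA2A were called lower and listed at 0 in both treated libraries, and MIR3648 was called higher with 1 untreated library listed at 0, so no fold is given for these small RNAs.

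Several other lists were called at 24 h, each lost with an estimated correlation. Heat shock genes had 7 of 18 falling and HSPB1 rising, 12 and 1 adjusted over the list alone (median -0.14, camera adjusted p = 1.52e-07, and adjusted p = 0.148 with an estimated correlation). Autophagy and lysosome genes had 8 of 21 rising, 11 adjusted over the list alone, among them the sialidase NEU1 (0.57) and the cathepsins CTSD (0.40) and CTSB (0.28; median 0.15, adjusted p = 0.00661, and adjusted p = 0.148 with an estimated correlation). T cell receptor genes had 8 of 22 rising, among them LAT (0.28), PLCG1 (0.25) and CD28 (0.24), and PTPRC falling, 9 and 2 adjusted over the list alone (median 0.11, adjusted p = 0.0469, and adjusted p = 0.274 with an estimated correlation). Fatty acid synthesis had 4 of 13 rising, 5 adjusted over the list alone (median 0.11, adjusted p = 0.0469, and adjusted p = 0.541 with an estimated correlation). MYC targets had 6 of 32 falling, 6 adjusted over the list alone (adjusted p = 0.00206, and adjusted p = 0.467 with an estimated correlation). Replication histones had no member called, over all genes or adjusted over the list alone (median -0.32, adjusted p = 0.0367, and adjusted p = 0.148 with an estimated correlation). HSPB1, CTSB, LAT and PTPRC were chosen after their values were seen.

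In total 1286 genes were higher and 692 lower at 24 h, 1978 calls with 3874 at an unadjusted p under 0.05, and all of these libraries ran in lane 4. The split was 758 higher and 984 lower after median centring, 951 and 957 after quantile normalization, and 1004 and 1236 after correction for GC content and length. Fold changes at 24 h followed the GC content of the gene (Spearman correlation of 0.44 across genes), and the second 25 µg/ml library deviated from the mean library with a correlation of 0.57 to GC content, against -0.37 in the second untreated one. Medians after the correction were 0.37 for cholesterol synthesis, -0.36 for G2/M, -0.19 for heat shock, 0.09 for autophagy and lysosome and 0.03 for T cell receptor genes. Without the second 25 µg/ml library 602 genes were called, without untreated replicates 1 and 2 at 24 h 1059 and 483, and without 12.5 µg/ml replicates 1 and 2 at 6 h 3071 and 3068.

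**Figure D2:**
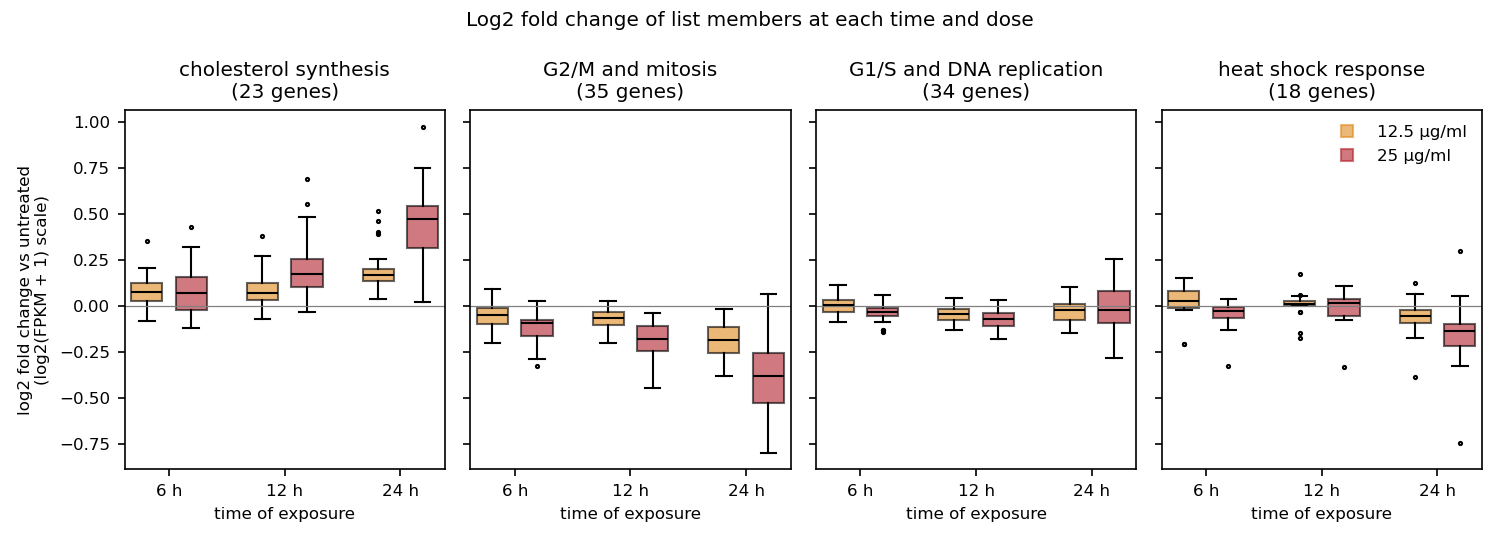
Log2 fold change against untreated cells (vertical axis) of the members of 4 gene lists as box plots (line, median; box, quartiles; whiskers, range without outlying members, which are small circles), at 12.5 and 25 µg/ml ILT3.Fc after 6, 12 and 24 h (horizontal axis). At 25 µg/ml and 24 h the median was 0.47 for cholesterol synthesis and -0.38 for G2/M.

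The difference between the effects of 25 µg/ml at 24 h and at 6 h was tested directly, to ask whether the response grew. Genes of cholesterol synthesis and mitosis were among those called. HMGCS1 rose by 0.65 more at 24 h (SE 0.058, limma adjusted p = 0.00289) and MSMO1 by 0.47 more (SE 0.084, adjusted p = 0.0182). HMMR (-0.47, SE 0.079, adjusted p = 0.0172), PLK1 (-0.40, SE 0.064, adjusted p = 0.0166) and CHORDC1 (-0.42, SE 0.080, adjusted p = 0.0237) fell more. MSMO1, HMMR and PLK1 lost these calls under 7 of 28 alternatives each (highest adjusted p 0.0855, 0.0847 and 0.074), CHORDC1 under 8 (0.108) and HMGCS1 under 1 (0.058). For the first 4 genes these included a fit of the groups compared alone and fits without single untreated or 25 µg/ml libraries at 6 or 24 h. The cholesterol synthesis list had 11 of 23 members with a larger rise, 19 adjusted over the list alone (camera adjusted p = 1.07e-14, and adjusted p = 0.00193 with an estimated correlation). The G2/M list had 18 of 35 with a larger fall, 26 adjusted over the list alone (adjusted p = 3.44e-22, and adjusted p = 0.00193 with an estimated correlation). PLAC8L1 (1.35), C6orf223 (0.95), LOC100288842 (0.97) and TNFSF9, the ligand of the co-stimulatory receptor 4-1BB (0.90, adjusted p = 0.0131), had more positive effects at 24 h. Levels of PLAC8L1 and TNFSF9 were low, with untreated means of 1.152 and 1.586 FPKM over all times. FAM72B (-0.58), HCG27 (-0.64) and the read-through gene GPR75-ASB3 (-0.86) had more negative ones. HCG27 lost its call under 20 of 27 alternatives, and the other 6 under 1 to 9. FAM72B and GPR75-ASB3 are uncertain, because near-identical or overlapping genes share reads, and RN5S3 was listed at 0 in both 25 µg/ml libraries at 24 h. Heat shock, MYC target and autophagy and lysosome lists were called too and lost with an estimated correlation (adjusted p = 0.443, 0.587 and 0.159 with an estimated correlation). Of 396 calls, 282 were more positive and 114 more negative, and 2603 genes had an unadjusted p under 0.05. The split was 149 and 125 after median centring, 206 and 176 after quantile normalization, and 161 and 233 after correction for GC content and length, which kept 192 of the 396. The calls numbered 5 and 66 without 25 µg/ml replicates 2 and 1 at 6 h, and 13 and 19 without untreated replicates 2 and 1 at 6 h. They numbered 33 and 227 without untreated replicates 2 and 1 at 24 h, and 18 and 845 without 25 µg/ml replicates 2 and 1 at 24 h. Among libraries of other groups, the count was 193 without either 12.5 µg/ml 12 h library, 196 and 197 without 25 µg/ml replicates 1 and 2 at 12 h, and 1162 and 1161 without 12.5 µg/ml replicates 1 and 2 at 6 h.

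The lower dose was compared with untreated cells to ask whether fewer micrograms gave the same response. At 12.5 µg/ml over all times SF3B3 fell by 0.33 (SE 0.020, limma adjusted p = 6.5e-05), HMMR by 0.25 (SE 0.035, adjusted p = 0.0276) and CHORDC1 by 0.25 (SE 0.035, adjusted p = 0.0276). PRMT10 rose by 0.35 (SE 0.029, adjusted p = 4.82e-04), HSD17B7 by 0.40 (SE 0.056, adjusted p = 0.0276) and HMGCS1 by 0.32 (SE 0.026, adjusted p = 4.82e-04), and C20orf197 (-0.27) and LOC100289187 (0.38) passed too. LOC100289187 lost its call under 24 of 31 alternatives, and of 32 alternatives CHORDC1 lost it under 19, HMMR under 18, HSD17B7 under 16, C20orf197 under 14, PRMT10 under 2 and SF3B3 under 1. The value of PLK1, -0.15, did not pass (adjusted p = 0.0636). Cholesterol synthesis rose with 4 of 23 members called, 13 adjusted over the list alone (median 0.11, camera adjusted p = 4.23e-14, and adjusted p = 0.00223 with an estimated correlation). G2/M fell with 4 of 35, 22 adjusted over the list alone (median -0.11, adjusted p = 1.17e-25, and adjusted p = 0.00223 with an estimated correlation). T cell receptor genes (0.04), glycolysis (0.04), ATF4 targets (0.05), SRF targets (0.05), ribosomal proteins (0.05) and G1/S (-0.03) were called with no member passing over all genes, and lost with an estimated correlation (adjusted p = 0.278 to 0.768 with an estimated correlation). The 34 calls, 20 higher and 14 lower, became 4 and 8 after median centring, 21 and 29 after quantile normalization, and 94 and 150 after correction for GC content and length. In this comparison 1315 genes had an unadjusted p under 0.05. Lane 4 alone gave 68 calls, 13 higher and 55 lower, with 6 of the 34 among them, and lane 5 alone gave 17, 9 higher and 8 lower, with 0 of the 34 (2463 and 1201 genes at an unadjusted limma p under 0.05). Leaving out any 1 of the 16 libraries that had a duplicate moved the count, to 70 and 895 without 12.5 µg/ml replicates 1 and 2 at 6 h and to between 4 and 20 without each of the others.

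At single times 12.5 µg/ml gave 3, 5 and 14 calls at 6, 12 and 24 h, with 919, 428 and 1167 genes at an unadjusted p under 0.05. The genes given here were partly chosen after their values were seen. At 6 h PRMT10 rose by 0.38 (limma adjusted p = 0.0218) and SF3B3 fell by 0.31 (adjusted p = 0.00765), and SNORA16B was called from untreated libraries listed at 0. At 12 h SF3B3 fell by 0.31 (adjusted p = 0.0244), and the other 4 were the small RNAs RNU1-4, RNU1-7, SCARNA15 and SNORA16B, of which the first pair are near-identical copies with identical values. At 24 h HMGCS1 (0.52, adjusted p = 9.16e-04), MSMO1 (0.40, adjusted p = 0.0369) and PRMT10 (0.35, adjusted p = 0.0346) rose. SF3B3 (-0.37), HMMR (-0.38), CHORDC1 (-0.39), PLK1 (-0.32), CENPA (-0.31), KIF20A (-0.29), TPX2, H1F0, SLC20A1 and ZNF256 were among the 11 that fell. Cholesterol synthesis had 2 of 23 members rising at 24 h, 13 adjusted over the list alone (median 0.17, camera adjusted p = 7.36e-18, and adjusted p = 9.49e-04 with an estimated correlation). G2/M had 5 of 35 falling, 23 adjusted over the list alone (median -0.18, adjusted p = 8.39e-34, and adjusted p = 8.47e-04 with an estimated correlation). In all 11 lists were called at 24 h, 7 of them higher, and only 2 with an estimated correlation. At 6 and 12 h 6 and 3 lists were called, and none with an estimated correlation. The 24 h split of 3 higher and 11 lower was 6 and 11 after quantile normalization and 55 and 104 after correction for GC content and length. Leaving out 1 library gave 2 to 4 calls at 6 h, but 5 without untreated replicate 2 at 6 h, and 6 and 2169 without 12.5 µg/ml replicates 1 and 2 at 6 h. At 12 h it gave 8 without either untreated 24 h library, 3 without either untreated 6 h library, 2 without either 12.5 µg/ml 24 h library, 1 without either 25 µg/ml 6 h library, 1 without 12.5 µg/ml replicate 2 at 12 h, and 5 to 7 otherwise. At 24 h it gave 65 without either 12.5 µg/ml 6 h library, 14 without the untreated 12 h library and 3 to 9 without each of the others.

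The doses were also compared with each other. HMGCS1 was higher at 25 than at 12.5 µg/ml by 0.34 (SE 0.024, limma adjusted p = 2.29e-04) and MSMO1 by 0.26 (SE 0.034, adjusted p = 0.0143), with C6orf223 (0.26) and CNNM4 (0.21) also higher. PLK1 was lower by 0.29 (-0.29, SE 0.026, adjusted p = 0.00175) and HMMR by 0.27 (-0.27, SE 0.032, adjusted p = 0.00558), with GPR17 (-0.39) also lower, and SNORA16B was listed at 0 in every 25 µg/ml library. Cholesterol synthesis had 5 of 23 members higher, 19 adjusted over the list alone (median 0.13, camera adjusted p = 1.5e-16, and adjusted p = 0.00125 with an estimated correlation). G2/M had 8 of 35 lower, 27 adjusted over the list alone (median -0.11, adjusted p = 9.04e-33, and adjusted p = 9.5e-04 with an estimated correlation). In all 9 lists were called by camera, 2 of them higher, and only 2 with an estimated correlation. The 34 calls were 8 higher and 26 lower, 4 and 31 after median centring and 65 and 142 after correction for GC content and length, and 1427 genes had an unadjusted p under 0.05. Lane 4 alone gave 28 calls, 20 higher and 8 lower, and lane 5 alone 18, 9 higher and 9 lower, and each held 1 of the 34. HMGCS1 was at 0.30 (adjusted p = 0.0568) and 0.28 (adjusted p = 0.0629) in lanes 4 and 5, and C6orf223 at 0.31 (adjusted p = 0.141) and 0.05 (adjusted p = 0.799). MSMO1, GPR17, PLK1, HMMR and CNNM4 passed in neither lane (adjusted p from 0.0629 to 0.529). Calls were lost under 27 of 32 alternatives for CNNM4, 20 of 32 for GPR17, 24 of 33 for C6orf223, 11 of 33 for MSMO1, and 6, 4 and 3 of 33 for HMMR, PLK1 and HMGCS1. Leaving out 1 library gave 59 and 1474 calls for 12.5 µg/ml replicates 1 and 2 at 6 h, 27 for 25 µg/ml replicate 1 at 24 h, 34 for the untreated 12 h library, and 9 to 22 for each of the others.

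All 34 genes called at 12.5 µg/ml were also called at 25 µg/ml, 20 higher and 14 lower at both. Both comparisons used the same untreated libraries. Independent lists of these sizes would share 1.09 higher and 0.56 lower genes, while part of the excess may come from the shared controls. Simulated unchanged groups shared 0 calls, which does not measure that part, since groups without change give few calls by construction. Across genes, which are not independent replicates, the fold changes at both doses correlated at 0.621, against 0.554 in the simulation, with a covariance of 0.0137 against 0.0115. The split that follows also left out the 12 h libraries and gave each dose 1 untreated library per time, so its values rest on fewer libraries. With the untreated libraries split between the doses, the correlations were 0.128 and 0.127, and 2 and 1 calls were shared. Without 12.5 µg/ml replicates 1 and 2 at 6 h there were 68 and 432 shared calls, the latter of 895 at 12.5 µg/ml, and without any other 1 of the 16 libraries that had a duplicate there were 3 to 20. Lane 4 alone shared 13 of 68 calls and lane 5 alone 3 of 17.

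Untreated cells were compared at 24 and 6 h, as the background of time in culture. PTCRA rose from 7.82 ± 0.459 to 13.6 ± 0.858 FPKM (SD, n = 2 each), by 0.73 on the log2 scale (SE 0.106, limma adjusted p = 0.0106). CEBPB, a leucine zipper transcription factor, rose from 4.52 ± 0.564 to 8.60 ± 0.80 FPKM (log2 change 0.80, SE 0.125, adjusted p = 0.012), and CMTM8 (0.72) and RN7SL1, the RNA of the signal recognition particle (1.07), rose too. RN7SL1 and CMTM8 lost their calls under 15 of 28 and 11 of 27 alternatives, and PTCRA and CEBPB under 6 of 28 each. MFI2-AS1 (-0.82, adjusted p = 0.00237), which cannot be told from its sense partner without strand, MYL5 (-0.73, lost under 16 of 28 alternatives), LOC100288842 (-0.85) and LOC100507167 (-0.84) fell. The G2/M list was called higher with no member called and 5 higher adjusted over the list alone (median 0.08, camera adjusted p = 3.21e-07, and adjusted p = 0.134 with an estimated correlation). ATF4 targets (0.06), NOTCH targets (0.05), heat shock genes (0.09) and ribosomal proteins (0.03) were called higher too and lost with an estimated correlation (adjusted p = 0.261 to 0.793 with an estimated correlation). The 280 calls were 67 higher and 213 lower, 115 and 150 after median centring, 150 and 207 after quantile normalization and 568 and 530 after correction for GC content and length. Here 2248 genes had an unadjusted p under 0.05. Without untreated replicates 1 and 2 at 24 h 39 and 8 genes were called, and without those at 6 h 13 and 8. Without 12.5 µg/ml replicates 1 and 2 at 12 h there were 157 and 160, and without 12.5 µg/ml replicates 1 and 2 at 6 h 796 and 795.

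**Figure D3:**
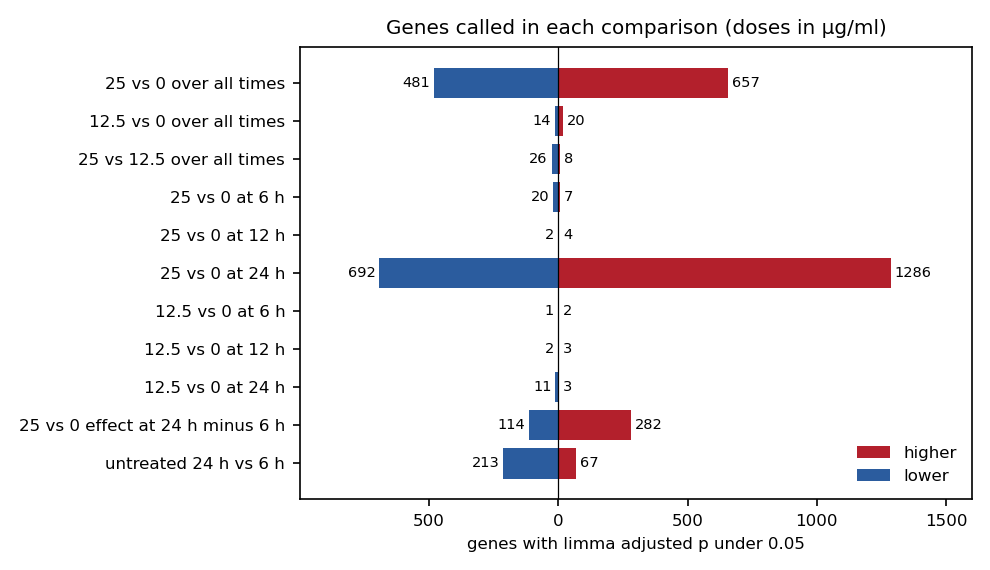
Number of genes with a limma adjusted p under 0.05 (horizontal axis, from 0 in both directions) that were higher (right) or lower (left) in each of 11 comparisons (vertical axis). The bars add up to 1138 for 25 against 0 µg/ml over all times and 1978 at 24 h, with the higher share depending on the scaling as given in the text.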

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

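The correction for GC content and length was added after seeing the data. The tests of GC content on the change between times, of the cycling share (within lanes too) and of lane at 24 h were chosen after the results were seen. The corrected list medians at 24 h were also brought in after that. The remaining tests were chosen before their own outcomes were seen. Those that used the correction, on cholesterol synthesis and mitotic genes, still came after the data had been examined.

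The effect of 25 µg/ml differed between 6 h and 24 h for 396 genes, which drew attention because the difference itself was tested. GC bias of single libraries may account for part of these calls, since after correction for GC content and length 192 of them were kept (104 more positive, 88 more negative). The difference itself followed GC content (Spearman correlation of 0.58 across genes), with 0.44 for the effect at 24 h and -0.34 at 6 h. Its median was 0.197 in GC-rich genes and -0.078 in GC-poor ones. The 204 calls that ended went from a median size of 0.39 to 0.21, with a median SE of 0.082 before and 0.074 after, so they ended with smaller changes and not with a larger spread. Another 202 genes were called only after the correction, 394 in all, so the number of calls hardly moved. A single aberrant 24 h library at 25 µg/ml is argued against as the whole cause, since without the second one 602 genes were still called at 24 h, against 21 at 6 h in the same fit, although the direct test of the difference then called 18 genes. A response that grows with time is the biological explanation in the design, and it stays open beside GC bias and a single aberrant library.

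The same difference was seen in single genes: HMMR (-0.47), CHORDC1 (-0.42), PLK1 (-0.40), HMGCS1 (0.65) and MSMO1 (0.47). After the correction these were -0.39, -0.31, -0.55, 0.72 and 0.54, and all still passed (limma adjusted p from 4.03e-04 to 0.00297), but HMMR, PLK1 and MSMO1 lost their calls under 7 of 28 alternatives, CHORDC1 under 8 and HMGCS1 under 1 (highest adjusted p 0.0847, 0.074, 0.0855, 0.108 and 0.058). The median change from 6 h to 24 h was 0.378 for cholesterol synthesis (0.31 after the correction), -0.256 for G2/M (-0.228), -0.123 for heat shock (-0.159), -0.027 for MYC targets (-0.133) and 0.174 for autophagy and lysosome genes. The last became 0.061 and was no longer called (camera adjusted p = 0.0849).

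Cholesterol synthesis genes rose at 25 µg/ml over all times, with a median of 0.222. After the correction the median was 0.211, but fold changes over all times followed GC content only weakly (Spearman correlation of 0.1 across genes), so there was little to correct. At 24 h, where that correlation was 0.44, the median went from 0.471 to 0.369. GC content and length are therefore argued against as the whole cause. A lane shift common to the doses would cancel in this contrast, because at each time every dose ran in the same lanes. The median was 0.253 in lane 4, which holds no 12 h library, and 0.088 in lane 5, which holds no 24 h library. A different size of response in the lanes therefore cannot be told apart from one at different times. Within the 24 h libraries, all in lane 4, the median was 0.471 (camera adjusted p = 2.62e-18), which lane cannot produce. A response of sterol synthesis to the fusion protein remains a hypothesis, and a control Fc protein was not analysed here.

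Mitotic genes fell at 25 µg/ml, with a median of -0.215 for the G2/M list. The corrected median was -0.22, although there was little to correct over all times. At 24 h, where fold changes followed GC content more, the median went from -0.381 to -0.356. GC content and length are therefore argued against as the whole cause. A lower share of cells in all phases of the cycle would lower replication genes to a similar degree, but the G1/S median lay 0.071 above 0.5 times the G2/M median (95% bootstrap interval over genes 0.032 to 0.115, from 10000 draws), and 0.104 above it in lane 4 (0.068 to 0.157). In lane 5, without 24 h libraries, the difference was -0.007 (-0.023 to 0.032), so a lower cycling share stays open there. These intervals treat list members as independent and hold no spread between libraries. A change within G2 and mitosis may remain, and no cell cycle profile was analysed here.

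Dose labels were exchanged within each time in 100 splits of the libraries, the real one included, with separate splits drawn for each comparison. At 25 µg/ml the real labels gave 1138 calls, with 273 at most in another split. They gave 34 against 4 at 12.5 µg/ml, 34 against 16 between the doses and 34 against 5 for the shared calls. A shared call must also be a call at 12.5 µg/ml, so the last count does not test sharing by itself. A chance sorting of these libraries is argued against for these counts. The labels do not say whether duplicates were separate cultures, so chance differences between cultures cannot be excluded. For the number of lists called, 6, chance sorting stays open, since 30 of the splits for 25 µg/ml gave as many or more and the highest other was 10.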

How the results depend on the processing

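Leaving out the 24 h libraries and correcting for GC content and length, with or without the replicate block, were chosen after seeing the data. The genes named for the largest changes at 25 µg/ml over all times had to keep 1 direction at all times, so their kept direction is partly fixed by that choice. The other named genes had no such condition. Of 4330 values of 139 called results for named genes under the alternatives, 3218 kept their call, 1111 kept only their direction and 1 turned, PFKL at 25 µg/ml over all times, which was -0.001 without the 24 h libraries. Another 36 results for named genes that were not called passed under some alternative. SF3B3 (-0.540 to -0.462, highest adjusted p 0.0411) and HMGCS1 (0.488 to 0.675, highest adjusted p 0.0269) were called under every alternative at 25 µg/ml over all times. PRMT10, HMMR, PLK1 and CHORDC1 were lost in lane 5 alone and kept under all others. The pseudocount of 0.1, the linear dose model (1125 calls at 25 µg/ml) and lane as a covariate moved no count by over 1.5 times. Except where the construction shows it, the cause was not tested. Absolute depth is unknown, so the lowest detectable change of single genes rests on the simulations alone.

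Counts are given for 25 µg/ml over all times (1138), 12.5 µg/ml over all times (34), 25 against 12.5 µg/ml (34), shared calls (34), 25 µg/ml at 6 h (27), 12 h (6) and 24 h (1978), 12.5 µg/ml at 6 h (3), 12 h (5) and 24 h (14), the difference between times (396), untreated cells (280) and lists called (6), where they moved. Correction for GC content and length gave 2127 at 25 µg/ml, 244 at 12.5 µg/ml, 207 between doses, 236 shared, 130 at 6 h, 87 at 12 h, 1 and 159 at 12.5 µg/ml at 12 and 24 h, and 1098 in untreated cells. Of the main calls it kept 1069 at 25 µg/ml over all times and 1350 at 24 h. No filter on low values gave 42 at 12 h, 8 and 24 at 12.5 µg/ml at 6 and 12 h, and 236 for the difference between times. A mean FPKM of at least 5 gave 10 at 12 h, and quantile normalization 13. Median centring gave 12 at 12.5 µg/ml, 12 shared, 12 at 6 h and 10 at 12 h. No variance trend gave 6 at 12.5 µg/ml, 6 shared, 9 at 6 h, and 1 and 4 at 12.5 µg/ml at 12 and 24 h. The additive model gave 16 at 12.5 µg/ml, 16 shared and 7 between doses. An estimated correlation left 2 lists, and fry called 15.

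Fits with fewer libraries have a less certain spread by construction. Only the groups compared gave 5 at 12.5 µg/ml, 11 between doses, 0 at 6 h by limma (1860 at an unadjusted p under 0.05), 12 at 24 h, 19 and 5 at 12.5 µg/ml at 12 and 24 h, 101 for the difference between times and 2 in untreated cells. Lane 4 alone gave 42 at 25 µg/ml, 68 at 12.5 µg/ml and 13 shared. Lane 5 alone gave 8, 17 and 3, with 18 between doses. Without the 12 h libraries there were 488 at 25 µg/ml, 6 at 12.5 µg/ml, 2 between doses and 4 shared, and without the 24 h libraries 46, 2, 4 and 2.

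The replicate numbers did not pair the samples (correlations of deviations from -0.183 to 0.032). The replicate block gave 599 at 25 µg/ml, 3 at 12.5 µg/ml, 6 between doses, 3 shared, 2 at 6 h, 1299 at 24 h, 1 and 2 at 12.5 µg/ml at 6 and 24 h, and 0 by limma for the difference between times and for untreated cells (2306 and 1717 at an unadjusted p under 0.05), so the named genes of both lost their calls there. With the GC and length correction the block gave 56 at 12.5 µg/ml, 99 between doses, 56 shared, 1, 2 and 60 at 12.5 µg/ml at 6, 12 and 24 h, and 188 for the difference between times. Neither fit moved another count by over 1.5 times.

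Leaving out each library in turn gave 613 to 2034 at 25 µg/ml over all times, 4 to 895 at 12.5 µg/ml, 9 to 1474 between doses, 3 to 432 shared, 3 to 93 at 6 h, 4 to 39 at 12 h, 483 to 3071 at 24 h, 2 to 2169, 1 to 8 and 3 to 65 at 12.5 µg/ml at 6, 12 and 24 h, 5 to 1162 for the difference between times, 8 to 796 in untreated cells and 6 to 7 lists. The libraries behind these moves are named beside the counts in the results. The highest values came without a 12.5 µg/ml 6 h library, except for 12.5 µg/ml at 12 h (either untreated 24 h library) and for lists (untreated replicate 1 at 24 h or 25 µg/ml replicate 1 at 6 h). Omitting either 12.5 µg/ml 6 h library takes the difference between that pair out of the shared spread, and omitting replicate 2 leaves replicate 1, the library that stood apart, alone in its group. A lone library is assumed to vary like the other groups, and no value over all times or at 12 h against untreated cells can be had without the only untreated 12 h library.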

Other observations

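The test of splicing factor genes was planned before its result was seen, the tests of dose proportionality after. At 24 h, where fold changes followed GC content, single genes of metabolism and immunity also changed at 25 µg/ml. ALDOC, a glycolytic aldolase of brain, rose by 0.84 (limma adjusted p = 3.05e-04), PFKFB4, which makes an activator of phosphofructokinase, by 0.55 (adjusted p = 0.00421), and PFKL by 0.50 (adjusted p = 6.11e-04), while the pyruvate dehydrogenase kinase gene PDK1 fell by 0.39 (adjusted p = 0.00105) and the lactate dehydrogenase gene LDHA by 0.19 (adjusted p = 0.0232). NR1H3, which encodes the oxysterol receptor LXR alpha, rose by 0.41 (adjusted p = 0.013) and its target ABCG1, a cholesterol exporter, by 0.37 (adjusted p = 0.0206). The AP-1 gene JUN (0.57) and the cytotoxic granule gene PRF1 (0.43) rose, and IER3 (-0.50) and the oncogene LMO1 (-0.54), chosen after its values were seen, fell. The glycolysis list had a median of 0.08 at 24 h and -0.005 after correction for GC content and length. Corrected values of these single genes are not given here. Without the 24 h libraries NR1H3 (-0.09), ABCG1 (-0.03), JUN (-0.03) and PFKL (-0.001) had the other sign. PRF1 (0.05), ALDOC (0.14), PFKFB4 (0.20), PDK1 (-0.07), LDHA (-0.04) and IER3 (-0.39) kept theirs. LPCAT3, also of the LXR list, was at -0.15 over all times and did not pass.

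Some markers of other blood cells were expressed in these libraries. Of the 3 tested members of the myeloid list, AIF1 was abundant, at a mean FPKM of 310, and its value of 0.03 at 24 h did not pass (limma adjusted p = 0.862). CD68 and CST3, at means of 2.43 and 11.7, rose at 24 h by 0.46 (adjusted p = 0.0357) and 0.40 (adjusted p = 0.0409). CD79A of the B cell list, at a mean of 39.5, had a value of 0.17 (adjusted p = 0.0772), and NKG7 of the NK list, at a mean of 5.2, rose by 0.49 (adjusted p = 0.0341). Without the 24 h libraries CD68, CST3 and NKG7 were at -0.04, -0.22 and -0.03, so their rise was not seen at the earlier times. These genes were chosen after their values were seen, and a source for them was not tested.

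Because SF3B3 had the smallest adjusted p among the falling genes, splicing factors and RNA-binding proteins were tested as a group, with a list written after SF3B3, HNRNPH3, DHX9, DHX15 and SAFB2 had been seen and leaving these out. Of 89 tested members 13 were called at 25 µg/ml over all times (1 higher and 12 lower, 14.6% against 9.5% of all genes), and random lists matched on expression gave a mean of 8 (permutation p = 0.0531). After correction for GC content and length there were 22, all lower, against 20.7 (permutation p = 0.412). These tests did not show that splicing factor genes were called more often than other genes. The direction of the calls was not tested, and a list that leaves out called genes excludes no response.

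Over the 1138 genes called at 25 µg/ml, the change at 12.5 µg/ml had a median ratio of 0.521 to that at 25 µg/ml and a slope of 0.578 on it. Shared untreated libraries pull such values up. The split fits that follow also left out the 12 h libraries and gave each dose 1 untreated library per time. With the untreated libraries split between the doses, the slope was 0.101 over genes called in the split fits (19 and 17 genes) and 0.471 over the 1138 genes, with 0.508 and 0.434 for the assignments. The second value was computed after the first had been seen, and its genes were chosen with the same controls. A response proportional to dose may hold, but these tests cannot decide it.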
